A study of Mus musculus with 2 samples.

How the data were processed

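RNA from PDGFRα+ cells of floxed and Sox9 PreASKO mice was hybridised with a biotin label to 1 array per group. Per the labels' protocols, the stromal vascular fraction was prepared with collagenase, stained with a PE-coupled PDGFRα antibody and sorted against an unstained aliquot, and total RNA was extracted. No exclusion of other cells by a further marker is named there. Per the series' design text each array held RNA pooled from 3 mice. The deposited table holds a value for each of 35556 probe sets on each array. The authors summarised the arrays with RMA, per the submitters' processing notes, a method that corrects background, makes the arrays' distributions alike and summarises the probes of a probe set on the log2 scale. No version, log base or filter is given in the sources used here, and log2 is taken from the values, which run from 1.23 to 13.8. The sorted values of the arrays differed by at most 0.111 and by a median of 0.0213, so the distributions were alike but not identical. RMA understates differences of dim genes, and making distributions alike would remove a change that touched most genes. In 758 genes (3.80%) both arrays held exactly the same value, at a median level of 3.77.

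Probe sets were named from the platform annotation supplied with the series, which can be old. Of the 35556 probe sets 21789 named 1 gene, 1621 named several and 12146 were not listed there and stayed unnamed here. Gene identifiers of 21698 of the 21789 were found in a RefSeq gene table of assembly GRCm38.p6, and none of their symbols needed a change. Only probe sets with 1 gene were used, which gave 19938 genes. For the 999 genes with several probe sets the one with the highest mean over both arrays was taken. No coordinates are given because the table names no genome build.

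The groups had 1 array each, so no test was made. The difference PreASKO minus floxed was taken per gene and set against the limit of 1.5-fold named in the series' design text. Gene lists, the naming rule and the alternatives were fixed before the data were examined. There were 26 lists with 497 genes, of which 467 had a value. A list with at least 4 measured members was described by its median and by that median's percentile among 10000 random lists of the same size, drawn within 20 bins of mean level. These percentiles describe these arrays, since genes are not replicates and genes of one pathway move together. The list of Y-linked genes had 3 measured members and no percentile. The list of the 4 study genes had a median of -0.19, at percentile 2.76.

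The genes named were Sox9, Meis1, Dlk1 and Pdgfra, then the 12 most positive and 12 most negative differences among genes whose higher array reached the median of that quantity over all genes (5.18, the level floor), leaving out unnamed predicted genes and small RNAs, then up to 3 members per list and direction above that floor. Other genes in the text, among them Mcm2, Rrm2, Tyms, Pparg, Cebpa, Pi16, Adipoq, Ucp1, Fos, Lyz2, Mrc1, Col3a1, Col1a2 and the dim members past 1.5-fold, were chosen after their values were seen.

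The alternatives were a level floor, a 2-fold limit, the mean over a gene's probe sets, all probe sets as features, centring on the median difference, a loess correction on the mean level (span 0.3), quantile normalization of the arrays, and unmatched random lists. The olfactory receptor genes as a background of silent genes, the floor set from them, and the raising of values below their 95th percentile to it, were added after seeing the data. The steps were tested on simulated data for 19938 genes with a spread of 0.235 and 200 genes changed. Of genes changed by 1 on the log2 scale 94.0% (up) and 98.0% (down) passed the 1.5-fold limit, as did 1.31% of unchanged genes in either direction. Lists of 20 genes shifted by 0.5 lay at the extremes of the random lists, and 1 of 60 unchanged lists lay outside the middle 95%. The simulation gave every gene the same normal spread and let genes vary independently. Its 1.31% is therefore not an error rate for these arrays, where 7.01% of the olfactory receptor genes passed the limit. Its unchanged lists likewise held no genes that move together. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.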

Results

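Gene expression was measured on microarrays in PDGFRα+ cells sorted from the stromal vascular fraction of the inguinal fat pad, the mixture of non-adipocyte cells left after collagenase digestion of this subcutaneous white fat. PDGFRα is a growth factor receptor of fibroblast-like cells that include adipocyte precursors. The cells came from female mice aged 6 weeks that carried either floxed Sox9 or the Sox9 PreASKO genotype, both given doxycycline at postnatal day 1. Sox9 encodes a transcription factor best known from cartilage formation. Each group was 1 array of RNA that the series' design text describes as a pool of 3 animals, so that 2 arrays were compared. No difference below has a replicate check, an error or a p-value. All differences are PreASKO minus floxed on the log2 scale of the deposited values. A difference of 0.585 corresponds to 1.5-fold, the limit the series itself names. The arrays had median values of 4.73 (floxed) and 4.71 (PreASKO) and correlated with r = 0.982 across 35556 probe sets.

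The first question was how the genes in the study's title stood in the sorted cells. Sox9 was at 5.25 in the floxed array and 4.97 in the PreASKO array, a difference of -0.27, which is smaller than the 1.5-fold limit. This difference lay at percentile 13.9 of genes with a similar mean level, so that Sox9 by itself did not separate the labels. The floxed Sox9 level stood at percentile 53.2 of all genes and at percentile 98.5 of 1027 olfactory receptor genes, which are taken as silent in these cells. Where its probes lie relative to the deleted part of the gene was not examined here. Meis1, a homeobox transcription factor, was at 7.35 and 7.24, a difference of -0.11. Dlk1, which encodes the preadipocyte protein Pref-1, was at 6.14 and 6.20, a difference of 0.07. Pdgfra, the gene of the sorting marker, was at 9.86 and 9.55, a difference of -0.31. None of these 4 genes differed by 1.5-fold.

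The series' own criterion was a change above 1.5-fold. Of 19938 genes, 331 were at least 1.5-fold higher and 394 at least 1.5-fold lower in PreASKO, together 3.64% of the genes. At the 2-fold limit 22 were higher and 29 lower. Dim genes carried most of the list: 457 of the 725 genes past 1.5-fold were below the level floor, the median of each gene's higher array (5.18). Above that floor 161 were higher and 107 lower, so that the balance between directions turned. Among the olfactory receptor genes 7.01% passed the same limit, 12 higher and 60 lower. The 95th percentile of these genes (4.64 in floxed and 4.47 in PreASKO) was used as a mark of background, the higher value for both arrays. Of the genes past 1.5-fold, 122 of the higher and 222 of the lower ones lay below this background in both arrays. With values below background raised to it, 161 genes were 1.5-fold higher and 103 lower; a fold against a value below background is given as "at least", computed in this way. Of the 4985 genes with the highest mean level 56 were higher and 19 lower.

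**Figure D1:**
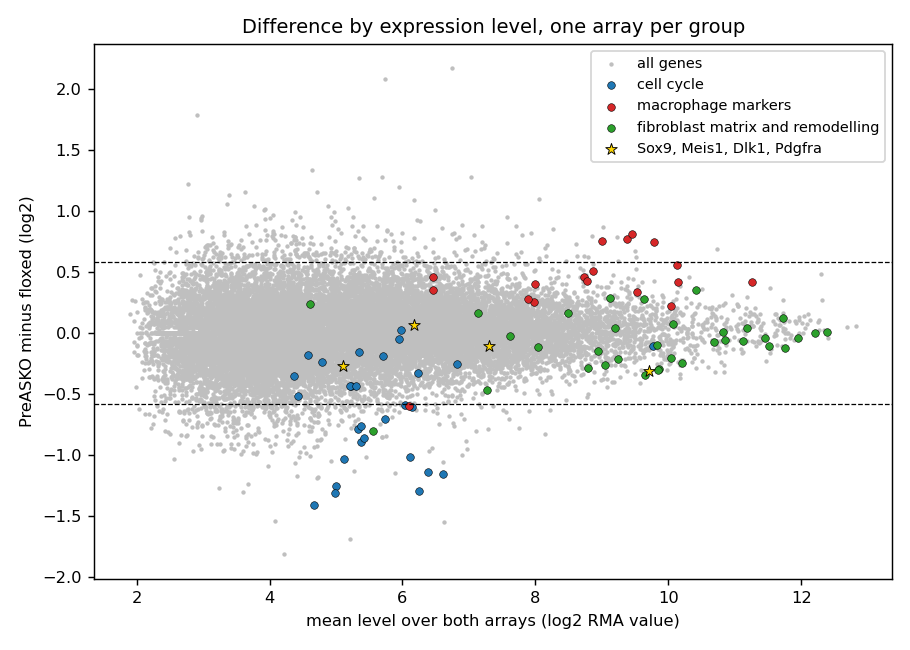
The log2 difference PreASKO minus floxed (vertical axis) is plotted against the mean log2 RMA value of both arrays (horizontal axis) for each of 19938 genes, with members of 3 gene lists and the 4 study genes coloured and the 1.5-fold limit dashed. Cell cycle genes sit below 0 with 1 exception, macrophage markers sit above 0 with 1 exception, and the study genes lie between the dashed lines.

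Cell cycle genes were lower in PreASKO. Of 29 measured members of the list, 28 were lower, 15 of them by at least 1.5-fold, and none was 1.5-fold higher. The median difference was -0.59, lower than in each of 10000 random lists matched on level, whose middle 95% ran from -0.09 to 0.12. Mki67, the proliferation antigen Ki-67, was at 6.90 and 5.60, a difference of -1.30. The cyclin gene Ccnb2 differed by -1.16. Plk1, a kinase of mitotic entry and spindle assembly, the spindle protein gene Tpx2 and the spindle checkpoint kinase gene Bub1b were below background in PreASKO and at least 1.66-fold, 1.995-fold and 1.99-fold lower. With the values of the list raised to background the median stayed at -0.59 and 15 members were 1.5-fold lower. Top2a, a topoisomerase of dividing cells, differed by -1.14 on its brighter probe set and by -0.04 on another. The genes of DNA replication and nucleotide supply in the list ran from Rrm2 (at least 1.98-fold lower) and Tyms (-0.59) to Mcm2 (-0.05) and Mcm5 (0.02). Among the 107 genes above the level floor that were 1.5-fold lower, 15 belonged to this list.

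Macrophage markers were higher in PreASKO. Of 18 measured members, 17 were higher, 4 of them by at least 1.5-fold, with a median difference of 0.42 that exceeded each of 10000 matched random lists. The antigen presentation genes H2-Ab1 (0.81) and Cd74 (0.75), the signalling adaptor Tyrobp (0.77) and the complement gene C1qa (0.75) passed the limit. The lysozyme gene Lyz2 was at 11.04 and 11.46 and the mannose receptor gene Mrc1 at 9.93 and 10.15, so both arrays held macrophage transcripts at high levels. The fractalkine receptor gene Cx3cr1 was the exception, with a difference of -0.60. Il1b, an inflammatory cytokine, was 2.42-fold higher (5.05 and 6.33), and the chemokine gene Ccl8 was 1.73-fold higher. The list of inflammatory cytokines and chemokines as a whole had a median of 0.09, at percentile 92.1 of random lists. Of its 23 measured members 2 were 1.5-fold higher and 1 was 1.5-fold lower, the acute-phase gene Saa3, which was below background in PreASKO and at least 1.28-fold lower.

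Interferon response genes had a median difference of 0.21 over 16 measured members, at percentile 99.9 of matched random lists, and none reached 1.5-fold. Rsad2, an antiviral enzyme gene, differed by 0.57, the oligoadenylate synthase gene Oas2 by 0.52 and the tethering factor gene Bst2 by 0.51. The macrophage markers were higher in the same array by a median of 0.42. Granulocyte and mast cell markers had a median of 0.19 over 12 members, at percentile 98.9, but only 3 members were above the level floor and their median was -0.15. With 7 members below background in both arrays, the median was 0 after values were raised to background. Lymphocyte markers had a median of 0.13 (percentile 95.02) over 14 measured members and of 0.39 over the 4 above the level floor, and 8 lay below background in both arrays. The median was 0 with values raised to background. Cd3e, a T cell receptor subunit gene, was higher by 0.88. The T cell genes Cd3g (0.12) and Cd8a (0.13), also above background in both arrays, differed less. Cd3d (-0.10) and Cd4 (-0.53) were below background in both arrays, as was the interleukin receptor gene Il7r, which passed the limit.

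The comparison of adipocyte precursor and adipocyte genes addressed the adipogenesis named in the series' title. No early progenitor marker and no commitment or preadipocyte marker differed by 1.5-fold, among 17 and 30 measured members. Their medians were -0.04 (percentile 10.2 of random lists) and -0.05 (percentile 5.70). Pparg, the master regulator of adipocyte differentiation, was at 7.95 and 7.88, and Cebpa, a second such regulator, was at 6.67 and 6.66. Dpp4 and Pi16, markers of early adipose progenitors, differed by -0.15 and -0.04. The largest differences among these lists above the level floor were Stat5b (0.46), the fatty acid transporter gene Cd36 (0.38), the tissue factor gene F3 (-0.38), and the semaphorin gene Sema3c (-0.34). Mature adipocyte and lipid storage genes had a median of 0.06 over 28 members (percentile 83.7), with the acyltransferase gene Agpat2 1.51-fold higher (4.65 and 5.24) and Scd1, a fatty acid desaturase gene, differing by 0.18. The floxed level of Agpat2 lay barely above the background mark of 4.64. Adiponectin (Adipoq) was at 4.55 and 4.40, below background in both. Thermogenic genes had a median of 0.14 over 12 members (percentile 95.5), 5 of them below background in both arrays. The median was 0.0323 with the mean over each gene's probe sets, 0 with values raised to background and 0.235 over the 6 members above the level floor. Cited1, a transcriptional coregulator, was 1.93-fold higher (7.09 and 8.04), Cox8b differed by 0.48, and Ucp1, the uncoupling protein gene of brown fat, was below background in both (3.04 and 2.86).

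Matrix genes of fibroblasts were nearly level. Of 34 measured members 1 was 1.5-fold lower and none 1.5-fold higher, with a median of -0.06. That median lay at percentile 0.39 of level-matched random lists and at percentile 9.82 of unmatched ones. Fmod, the collagen-binding proteoglycan fibromodulin, was 1.75-fold lower (5.96 and 5.15), and the matrix protein gene Tnc differed by -0.47 and Col6a2 by -0.34. The protease inhibitor genes Timp3 and Timp1 differed by 0.35 and 0.28. Collagen genes at high levels were not alike. Col3a1 differed by 0.04, Col1a2 by -0.05 and Col6a3 by -0.07, but Col14a1 by -0.31, Col6a1 by -0.30 and Col1a1 by -0.21. Chondrogenic genes and SOX9 targets had a median of -0.13 over 24 members (percentile 3.25; percentile 0.98 of unmatched lists), and of 0 with values raised to background. None reached 1.5-fold, 14 were below background in both arrays, and the 6 above the level floor were all lower, including Cilp (-0.40), Col9a3 (-0.30) and Col2a1 (-0.22). Of these 6, Col9a3, Col2a1, Col11a2 and Sox5 were dim. Their floxed levels lay below 5.43, the 99th percentile of the olfactory receptor genes in that array. Col9a3 (5.09) and Col2a1 (5.11) were below the level floor in PreASKO.

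The signalling and homeobox lists lay within the middle 95% of matched random lists. Wnt pathway genes had a median of -0.04 over 30 members and TGF-beta and BMP genes -0.03 over 30. Notch and hedgehog genes had a median of 0 over 19 members, and Meis, Pbx and Hox homeobox genes -0.09 over 26. The Wnt agonist gene Rspo1 differed by -0.53, and the secreted Wnt modulators Sfrp1 and Sfrp4 by -0.44 and -0.37. The 2 probe sets of Wnt4 differed in direction, 0.34 and -0.34. Smo, the hedgehog signal transducer, differed by 0.54 and Tgfb1 by 0.46. The members past 1.5-fold, Sfrp5 and Gdf5, were below background in both arrays. Among homeobox genes Pknox1 differed by 0.42, Hoxc6 by -0.40 and Pbx2 by -0.39.

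Markers of the other cell types a PDGFRα sort could hold differed in both directions. Mural cell markers had a median of -0.20 over 13 members, at percentile 0.85, with the potassium channel gene Kcnj8 1.54-fold lower, Acta2, smooth muscle actin, differing by -0.44 and Abcc9 by -0.41. In the other direction Notch3 differed by 0.46 (5.31 and 5.77), above background in both arrays. The contractile gene Cnn1 passed the limit in that direction but was below background in both arrays. With values raised to background 7 mural markers were lower and 3 higher. Endothelial markers had a median of 0.07 (percentile 83.6), with the VEGF receptor gene Kdr 1.61-fold lower. The medians were 0.11 for mammary and other epithelial markers (percentile 96.1; 0.2996 over the 4 above the level floor), 0.10 for mesothelial markers (percentile 89.4), 0.09 for skeletal muscle markers (percentile 85.1; the troponin gene Tnnt3 differed by 0.76), 0.02 for Schwann cell and neural markers (percentile 56.3) and -0.05 for 4 erythroid markers (percentile 43.2). Of these, 13 of 18 epithelial, 7 of 8 mesothelial and all 4 erythroid markers were below background in both arrays, among them the keratin gene Krt17, which passed the 1.5-fold limit. Immediate early and dissociation stress genes were high in both arrays, with a median of 0.02 over 23 members (percentile 40.8) and none past 1.5-fold. Fos was at 11.1 in both. The 3 measured Y-linked genes lay between 2.38 and 3.10 in these female cells. Of the 25 lists that were ranked, 6 lay outside the middle 95% of random lists, against 1.25 for lists of random genes. Genes of one list can move together, so the 1.25 is no standard for these lists.

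**Figure D2:**
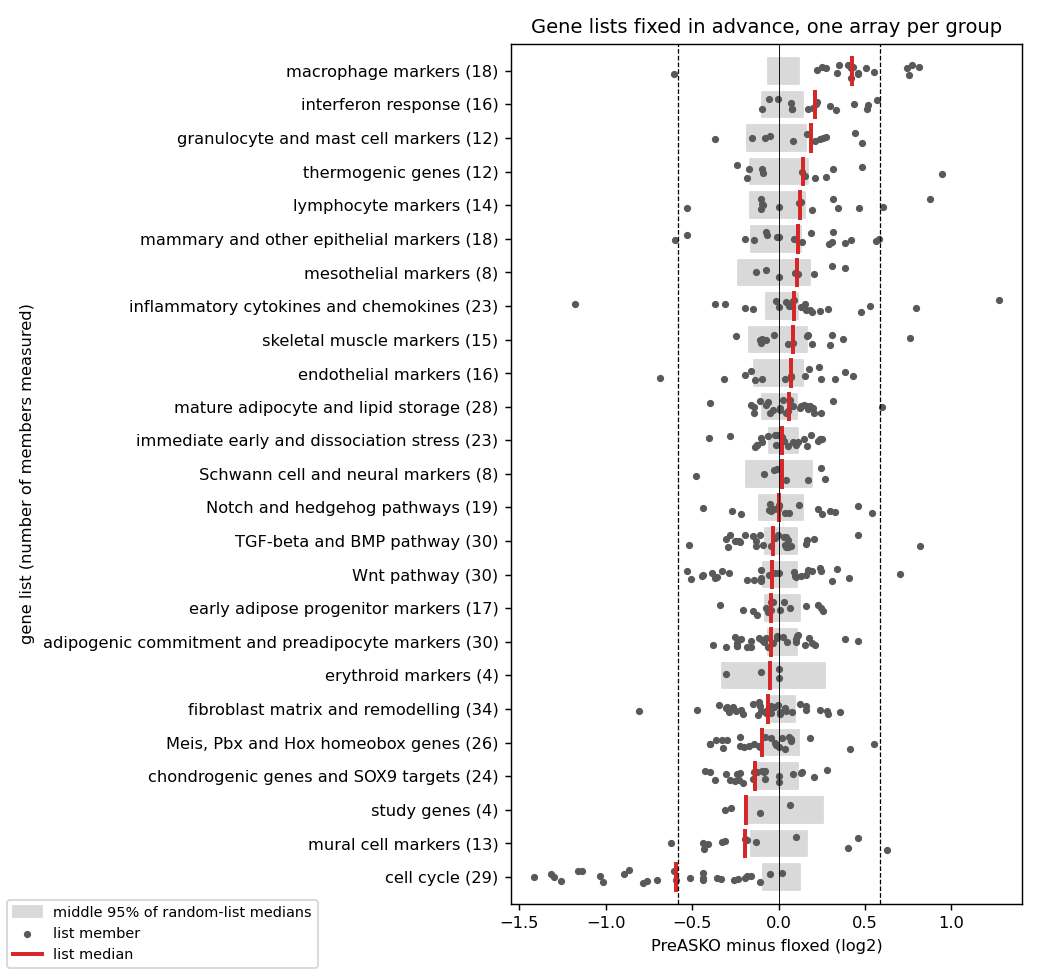
Each point is the log2 difference PreASKO minus floxed of 1 gene in the 25 lists ranked, with the list's median as a red bar, the middle 95% of medians of 10000 level-matched random lists in grey and the 1.5-fold limit dashed. Cell cycle (-0.59) and macrophage markers (0.42) have the medians farthest from 0.

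The genes with the most positive differences above the level floor included several immune genes. Glycam1, a mucin-like ligand of lymph node vessels that is also made by mammary epithelium, was 4.51-fold higher (5.66 and 7.84). Rnase2a, an eosinophil-associated ribonuclease gene, was 4.24-fold higher (4.69 and 6.78). The C-type lectin genes Clec4b1 (2.30-fold), Cd209d (2.14-fold) and Cd209a (2.01-fold) and the cytokine gene Il1b were also higher. Cd209 genes form a family of close copies, so that their probe sets can share signal. The others were Gxylt1 (1.27), the transferrin receptor gene Tfrc (1.10), Mrgprg (1.09) and Hinfp (1.03), with the ribosomal RNA methyltransferase gene Dimt1 (at least 1.56-fold) and Mn1 (at least 1.70-fold), which were below background in floxed. The floxed levels of Rnase2a (4.69), Gxylt1 (4.71) and Hinfp (4.67) lay just above the background mark of 4.64, so their folds are uncertain. Those of Il1b (5.05), Tfrc (5.02) and Clec4b1 (5.34) were below 5.43, the 99th percentile of the olfactory receptor genes in that array. Among the 12 genes with the most negative differences, 6 were below background in PreASKO, so that their order is not measured. Prc1, a microtubule cross-linker of cell division, was at least 2.66-fold lower (6.05 and 4.36). Thbs4, a matrix thrombospondin, was 2.93-fold lower (7.39 and 5.84). Mki67, Plk1, Tpx2, Bub1b, Ccnb2 and Top2a of the cell cycle list were also among them, as was Trip13 (at least 1.59-fold), a regulator of the spindle checkpoint. The rest were Olfr412 (at least 1.59-fold), an olfactory receptor gene, Rab6b (-1.13) and Chmp1a (-1.06).

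**Figure D3:**
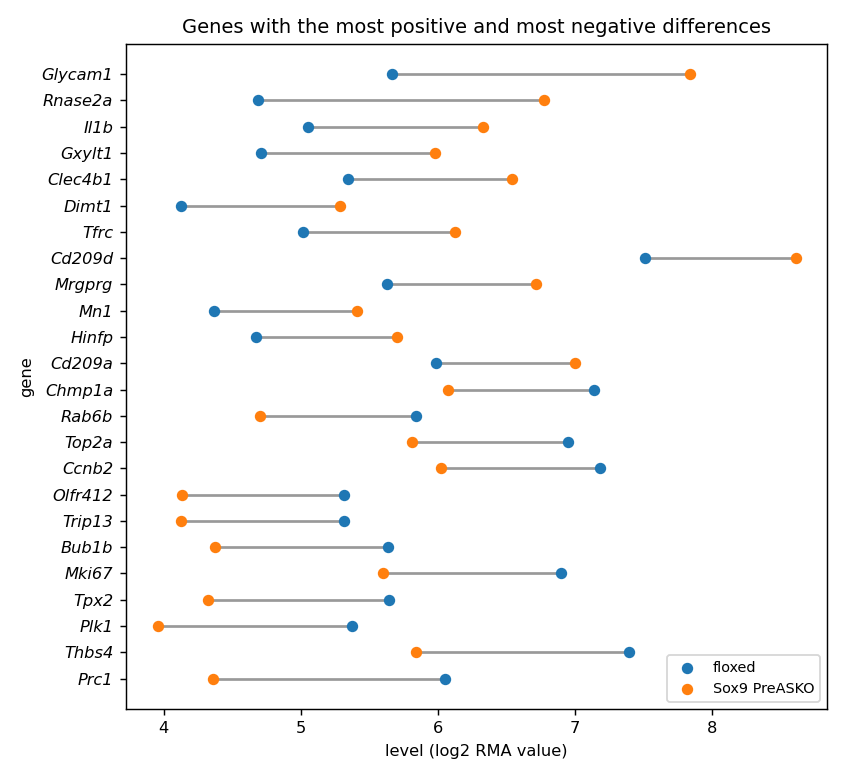
Levels (log2 RMA value, horizontal axis) of the 12 genes with the most positive and the 12 with the most negative difference above the level floor are shown for the floxed (blue) and PreASKO (orange) array, joined by a line. The longest lines are those of Glycam1 (5.66 and 7.84) and Rnase2a (4.69 and 6.78).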

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

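The counts of genes past the limit depended on the level floor, the fold limit and the use of every probe set. The 331 higher and 394 lower genes became 161 and 107 with the level floor, 22 and 29 at 2-fold, 1608 and 1982 over every probe set, named or not, and 207 and 164 with a floor at the 95th percentile of olfactory receptor genes. They became 161 and 103 with values below that percentile raised to it. These olfactory receptor settings were chosen after seeing the data. After loess correction the counts were 356 and 355 and after quantile normalization 374 and 343, so which direction had more genes turned with the scaling. Centring moved nothing, because the median difference was already 0. The 24 genes with the most positive and negative differences kept their direction and stayed past 1.5-fold under the rescalings and under the mean over probe sets, where Top2a moved to -0.59. With values raised to background they also stayed past 1.5-fold, with Plk1 at -0.727. The 4 study genes moved by less than 0.1 everywhere. Taking the mean over probe sets moved the thermogenic median from 0.143 to 0.0323, and keeping members above the level floor moved it to 0.235. Keeping members above the level floor moved the medians of cell cycle genes to -0.705, of mural markers to -0.313, of lymphocyte markers to 0.391, of epithelial markers to 0.2996, of 1 mesothelial marker to 0.307 and of granulocyte and mast cell markers from 0.1853 to -0.153. Raising values to background moved the medians of the thermogenic, chondrogenic, lymphocyte, granulocyte and mast cell, epithelial and mesothelial lists to 0.0, and left those of the cell cycle and macrophage lists where they were. The mature adipocyte, Wnt, TGF-beta and BMP, erythroid, endothelial and skeletal muscle medians, which had been nearer 0, also became 0. With unmatched random lists the matrix list moved inside the middle 95% and the chondrogenic list outside it. The causes of these shifts were not tested beyond the construction of each setting. No replicate could be left out, and no paired analysis was possible because each group has 1 array.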

Other observations

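Beyond the lists fixed in advance, further gene groups were examined after the first results had been seen. The MHC class II genes not yet named had a median of 0.52 over 4 members, and of 0.317 with values raised to background. Of these, 2 were below background in both arrays and cannot be called higher. The others, H2-Aa (0.77) and H2-Eb1 (0.63), were higher in PreASKO, though their family members can share probe signal. Markers of dendritic cells gave no clear direction, with a median of -0.13 over 8 members and of 0.23 over the 4 above the level floor; the other 4 were below background in both arrays. Of 5 eosinophil markers 4 were below background in both arrays. Cholesterol synthesis genes had a median of 0.14 over 10 members, at percentile 94.6 of random lists, with the farnesyl diphosphate synthase gene Fdps at 0.66. Complement genes of stromal cells (-0.02 over 6 members) and genes of FGF and PDGF signalling (0.02 over 16 members, with a mean of -0.01) were near 0.

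Of the tests below, those of dilution by macrophages, of the number of arrays, of the mural markers and with values raised to background were chosen after the result was seen. The predictions of the other tests were written before their own results. The second lists, the tendon and fascia list and the olfactory receptor background were themselves added after the first results had been seen. The lower cell cycle genes were not removed by rescaling: the median nearest 0 after loess or quantile normalization was -0.607. The arrays' distributions were already alike, however. Loess moved no gene by more than 0.0427, and quantile normalization moved genes by a median of 0.0198. This test could hardly have come out otherwise and decides little. Scatter of dim probe sets was tested with a second list of 31 mitosis genes not looked at before; its median was -0.53, with 12 members 1.5-fold lower, at percentile 0 of matched random lists, below every one of them. With values raised to background its median was -0.312, with 5 members 1.5-fold lower, and again below every random list. Dilution of the sorted cells by macrophages would lower fibroblast genes as far, but their median was -0.063 and their lower quartile (-0.22) lay above the upper quartile of the cell cycle list (-0.26). Sox9 deletion and chance variation between the pools cannot be told apart with 1 array per group, and a different share of dividing cells in the sorted pools remains open.

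The higher macrophage markers were also not removed by rescaling, with a smallest median of 0.408, a test limited in the same way. A candidate explanation is a larger share of macrophages among the sorted cells. A second list of 22 macrophage genes, sharing none with the first, had a median of 0.493 (0.471 with values raised to background). With values raised to background 21 had a difference above 0, the smallest only 0.03 (Ncf4), and 1 lay below background in both arrays. Of the 22 genes 7 were 1.5-fold higher, Ccl6 (0.78) and Fcer1g (0.59) among the abundant ones. A lower share of PDGFRα+ cells that raised all other cell types alike would raise the mural markers too. Those above the level floor had an upper quartile of -0.156, against a lower quartile of 0.34 for macrophage markers. Of these 7 mural markers 6 were lower and 1, Notch3 (0.46), was higher. Stromal cells also express some of these mural markers, so their levels need not follow the mural cells and the test cannot decide. Above the same floor the medians of other cell types went both ways: 0.39 for lymphocyte, 0.2996 for epithelial and 0.15 for endothelial markers, but -0.153 for granulocyte and mast cell and -0.03 for Schwann cell and neural markers. These rest on 3 to 7 genes each. The lymphocyte value lies between those of Ptprc (0.47) and Cd52 (0.31), which are not confined to lymphocytes. Cd3e (0.88) was higher and Cd79b (-0.09) was not, while the T cell genes Cd3g (0.12) and Cd8a (0.13), below that floor, differed less than Cd3e. The endothelial value is that of Fabp4, also an adipocyte lineage gene, while Kdr (-0.69) and Tek (-0.20) were lower. Pdgfra differed by -0.31, in the direction a lower share would give. The matrix genes had a median of only -0.063 and the early progenitor markers of -0.04. The size of the Pdgfra difference was thus not shared by these lists as a whole. Single matrix genes came close to it, such as Col14a1 (-0.31) and Col6a2 (-0.34), while 12 of the 34 matrix genes were higher. A lower share of PDGFRα+ cells, with or without fewer mural cells, stays open. A higher expression per macrophage, a different loss of cells in the sort and Sox9 deletion itself stay open, and the protocols name only the PDGFRα gate.

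The near-level Sox9 signal might come from a level close to the array's background. The floxed level stood at percentile 98.539 of olfactory receptor genes, between the bounds of 95 and 99 set for the decision, so background cannot be told apart from a true small difference. Probes outside the deleted part of Sox9 stay possible as well, because their position was not examined. The olfactory receptor genes had a median difference of -0.08, with 595 lower and 346 higher, against a median of -0.02 in 2931 other genes of similar level.

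A hypothesis from the cell cycle list was that mitosis genes differed further than DNA replication genes. In that list the kinds overlapped, with the replication gene Rrm2 at least 1.98-fold lower and the mitosis gene Cdc20 at -0.19. In second lists of genes not looked at before, the median of mitosis genes minus that of 24 replication genes was -0.425 (-0.53 and -0.10), in the predicted direction, and -0.312 with values raised to background. The replication list lay at percentile 2.96 of matched random lists and the mitosis list below all of them. These arrays are consistent with a difference in mitotic transcripts in particular, without showing it for the groups.

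A further hypothesis was that Thbs4, Fmod and Kera (7.39 and 6.39), matrix genes abundant in tendon and fascia, belonged to a wider group that was lower in PreASKO. A list of 10 other tendon and fascia genes lay at percentile 50.24 of matched random lists, with a median of 0.00 and a mean of -0.04. Its members went both ways, 4 were below background in both arrays and 1 in floxed, so the list decides nothing and the hypothesis stays open. Col12a1 was lower by 0.60 on the log2 scale and Scx, the tendon transcription factor, was below background in floxed and at least 1.12-fold higher.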
